A study of Ruditapes philippinarum with 24 samples.

How the data were processed

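RNA from pooled haemocytes was hybridised to 24 1-colour (Cy3) arrays of an Agilent design for the Manila clam and scanned in Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited scanner files hold, for each spot, a processed signal, a mean and a local background intensity, and flags. Per the file headers the processed signals were corrected for background by the scanner software and not normalized between arrays. Each array listed 14207 spots, of which 536 were control spots and 13671 were probes. Per the file headers, 3 slides held 8 arrays each and were scanned on 2 days, slides 1 and 2 in scan 1 and slide 3 in scan 2. No spot was saturated, and signals ran from 1.21 to 645570 intensity units.

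The deposited table of the whole series holds log2 values by the authors, normalized in GeneSpring per the labels' protocols. It covered 12916 of the 13671 probes. Set against the scanner files, its values were log2 processed signals with 1 constant per array, centred on each probe's median over the arrays, and the differences that remained had an SD of 0.000575. The scaling constant that the authors used is not given in the sources used here. Column medians were -0.073 for the control array of day 5, 0.080, 0.036 and 0.59 for the challenged arrays of day 5, -0.22, 0.19, -0.15 and -0.25 for controls of day 10, and -0.15, -0.0059 and -0.13 for challenged clams of day 10. They were -0.26, 0.10 and -0.011 for controls of day 14, -0.057, 0.25, 0.14 and -0.027 for challenged clams of day 14, -0.12 and 0.57 for controls of day 31, and 0.11, 0.16, -0.16 and -0.19 for challenged clams of day 31. For 2 of the 24 columns, the labels of challenged day 14 replicates 2 and 3 were exchanged relative to the scanner files (r = 0.23 with the own array and 0.9999 with the other), which changes no comparison of groups. The table served as an alternative only.

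In the values used, 30 spots marked as outliers were left out, control spots were removed, and log2 of the processed signal minus the 75th percentile of the array was taken. A probe was tested if it was well above background on at least 3 of the 24 arrays, which left 9549 probes. Of the 13671 probes, 5505 were well above background on every array and 2560 on none. They held 13330 distinct sequences, and spots of the same sequence on 1 array had a median SD of 0.33 log2. Median probe GC content was 36.7%. Each of the 8 groups had its own mean in 1 limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes), with 16 residual degrees of freedom and 2.42 prior degrees of freedom. All groups thus shared 1 estimate of spread. The shared effect of challenge came from a model of day plus challenge, and differences between days from moderated F tests over 3 contrasts. P-values were adjusted by Benjamini-Hochberg over the probes of a comparison, with a threshold of 0.05. For counts at an unadjusted p under 0.05, chance alone gives about 477 of 9549 probes.

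Samples were grouped by their titles. Replicate numbers in the titles were checked for pairing: in the 8 same-numbered pairs of days 10, 14 and 31, deviations from the group means correlated at r = -0.15 to 0.061, and 0 pairs exceeded 0.1, so the numbers were not treated as pairs. Where no array of a group had the probe well above background, the fold is a bound, computed from the mean log2 of the brighter group against, on each array of the other group, the higher of the lowest signal among detected probes and the probe's own signal. Undetected probes can lie above that lowest signal, so the bound is approximate. The tests of the comparisons, the gene lists, the rule for named probes and all alternatives but 2 were set before the data were examined. Several tests of explanations were chosen after the results were seen and are listed in the closing sections. For probes without names the rule allowed at most 2 that rose and 2 that fell per comparison. The largest changes were taken among probes that passed with no overlap between the arrays of both groups on days with 2 or more arrays each. For F tests, the 2 smallest p-values were taken. The 754 probes named after sequence database entries were tested but not named, a choice made after the data were examined. Probe sequences were matched to no genome, so no position is given. A sequence is printed only for a probe that was detected in control clams.

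The fits were tested on 1 run of simulated data per comparison, with 200 changed probes. Each of the 9549 probes had independent normal noise with its real spread. For day 14, 96% of changes of 6 in log2, 92% of changes of 4, 40% of changes of 2 and 14% of changes of 1 were recovered. For day 5 the shares were 94%, 70%, 24% and 0%, for day 10 they were 92%, 78%, 54% and 12%, and for day 31 they were 94%, 70%, 50% and 16%. For the shared effect they were 100%, 94%, 78% and 38%. Among the unchanged probes of these simulations, 3, 8, 4 and 11 were called on days 5, 10, 14 and 31, and 5 for the shared effect, beside the recovered ones. Simulated arrays without any change gave 0 calls in each comparison. Real probes varied together in sets, and the real comparisons called far fewer probes than 200. These shares and counts thus hold for the simulated setting alone.

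Alternatives were quantile normalization, centring on the median, normexp background correction with an offset of 50, a floor at the lowest detectable signal, other filters on dim probes, the deposited table, array weights, slide as a block, a minimum log2 change of 1, 1 value per entry of the gene name column, the arrays of 1 day alone, the replicate number as a block and leaving out each array. After the data were seen, the fit without the 2 dim arrays and that with 1 value per distinct sequence were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The gene name column of the files holds probe identifiers, so no gene name and no gene list was used. The biological identity of the probes is not analysed here.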

Results

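Gene expression was measured in haemocytes, the circulating blood cells of the Manila clam, after an injection of the protozoan parasite Perkinsus olseni. Clams received 100 µl of filtered sea water, as controls, or 100 µl of a suspension of parasite trophozoites, the stage that multiplies inside the host, at 50000 cells per ml. Each arm held 100 clams, of which 20 were sampled on each of days 5, 10, 14 and 31, and haemolymph was pooled before RNA extraction. The wording on pool size is ambiguous, so the number of clams in a pool is not stated here. Each pool was hybridised to a 1-colour array of 13671 probes of 60 bases.

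The 24 arrays fell into 8 groups. Controls had 1 array on day 5, 4 on day 10, 3 on day 14 and 2 on day 31, and challenged clams had 3 on day 5, 3 on day 10, 4 on day 14 and 4 on day 31. Between 6585 and 8692 probes per array lay well above background. The 75th percentile of the signal was 70.1 on control day 31 replicate 2 and 79.1 on challenged day 5 replicate 3, and lay between 154 and 377 on the other arrays. An alternative chosen after the data were seen, without these 2 arrays, called 9, 1, 67 and 11 probes on days 5, 10, 14 and 31, where all 24 arrays called 24, 7, 56 and 6. Arrays of the same group correlated at r = 0.88 to 0.94 over the 9549 probes tested, a correlation across probes, which are not independent replicates. The median r of each array with all other arrays was 0.89 to 0.91, inside that range, so the range shows no closer likeness within groups. P-values measure the spread between pools as labelled, and the number of arrays limits the precision.

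**Figure D1:**
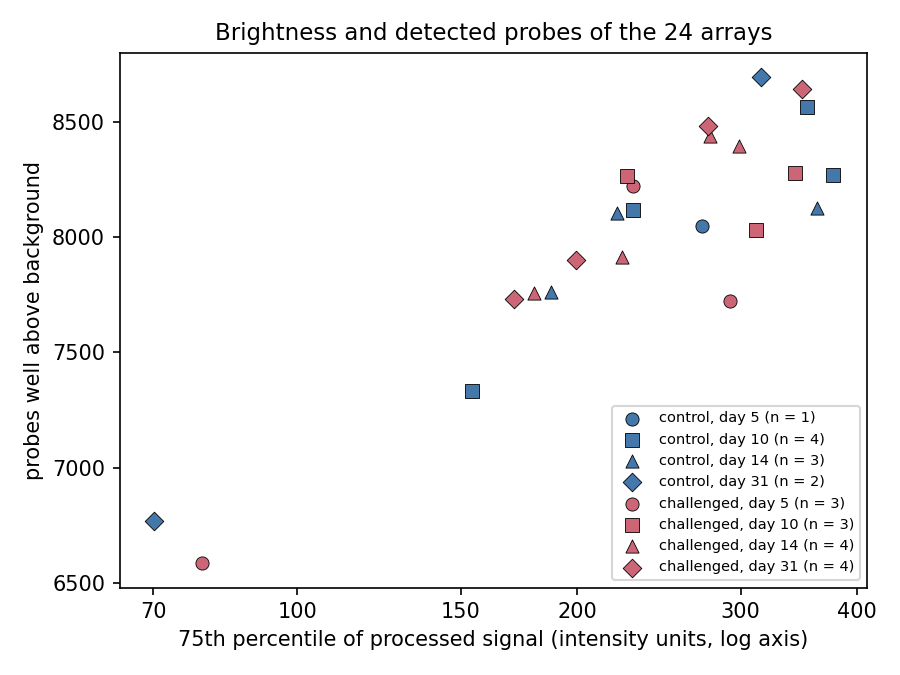
Number of probes well above background (vertical axis) against the 75th percentile of the processed signal in intensity units (horizontal log axis) for each of the 24 arrays, coloured by arm and shaped by day. Challenged day 5 replicate 3 (6585 probes) and control day 31 replicate 2 (6768 probes) sit apart at the dim end.

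None of the 13671 probes carried a gene or protein name, and 0 matched the 48037 genes of the reference table. The 30 gene lists fixed in advance, which covered lectins, Toll and NF-kB signalling, apoptosis, protease inhibitors, stress proteins, markers of other tissues and parasite transcripts among others, therefore matched 0 probes and were not tested. Probes are given by their identifiers, with at most 2 that were higher and 2 that were lower in challenged clams in each comparison. Signals are log2 values relative to the 75th percentile of their array, with the SD between pools.

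The comparison on day 5 set 3 challenged pools against 1 control array, which was assumed to vary like the arrays of the other groups, so challenge and that 1 pool cannot be separated. Of 9546 probes with a value, 24 passed limma's test, 16 higher and 8 lower in challenged clams. P_isotig17729_isogroup06196 was detected in the 3 challenged pools of day 5 alone, which is how it met the filter of 3 arrays. Its spread in the fit thus rests largely on signals below detection. It was higher in challenged clams, at -6.80 on the control array and 1.58 ± 0.72 (SD, n = 3) in challenged pools, and was well above background in each of the 3 challenged pools but not in the control. That was at least 96.7-fold, bounded by the lowest detectable signal of the control array (limma adjusted p = 2.54e-07), and the 6 groups of the other days, at -6.82 to -5.58, were below detection too. P_isotig07836_isogroup00628 was at -6.02 on the control array and at 2.06 ± 0.53 (SD, n = 3) in challenged pools, at least 134.5-fold higher (limma adjusted p = 0.0145). Here the control array departed, since the groups of the other days lay at 0.47 to 1.46 and were detected on all 20 arrays. P_isotig25702_isogroup14169, whose sequence is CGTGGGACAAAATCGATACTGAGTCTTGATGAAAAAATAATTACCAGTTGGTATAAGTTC, was at 4.74 on the control array and below detection in all 3 challenged pools, at -5.99 ± 0.89 (SD, n = 3). The control was at least 512-fold higher (limma adjusted p = 0.026). N_isotig15397_isogroup03864 was at 6.35 on the control array and 1.24 ± 0.67 (SD, n = 3) in challenged pools, a difference of -5.11 ± 0.96 (SE) in log2 (limma adjusted p = 0.0321). The control array departed again, since the groups of the other days lay at 0.63 to 1.93.

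No slide held both groups of day 5. With slide as a block 14 probes were called, and the adjusted p of N_isotig15397_isogroup03864 was 0.0624. The count was 9 without challenged day 5 replicate 2, 15 without challenged day 10 replicate 3 and 14 without challenged day 31 replicate 1, and a limma fit of the 4 arrays of day 5 alone gave 0 (670 at an unadjusted p under 0.05). The call of P_isotig25702_isogroup14169 ended without challenged day 5 replicates 1 or 2 (adjusted p = 0.0505 or 0.0736). A floor at the lowest detectable signal gave 36 calls on day 5 and turned their balance, with 14 higher and 22 lower in challenged clams.

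On day 10, 7 of 9549 probes differed, 2 higher and 5 lower in challenged clams. P_isotig11699_isogroup01992 was higher in challenged clams by 3.77 ± 0.53 (SE) on the log2 scale, from -4.95 ± 0.78 (SD, n = 4) to -1.19 ± 0.41 (SD, n = 3), with 3 of 3 challenged pools and 1 of 4 controls well above background (limma adjusted p = 0.0104), while the 6 groups of the other days lay between, at -3.21 to -1.39. P_GIDV13C01BU2ZY, bright in all 7 pools, was higher by 1.61 ± 0.28 (SE), from 4.56 ± 0.48 (SD, n = 4) to 6.18 ± 0.18 (SD, n = 3; limma adjusted p = 0.0408), with the other groups between, at 5.13 to 5.85. P_isotig06913_isogroup00450, also detected in all 7 pools, fell by 4.46 ± 0.74 (SE), from 6.22 ± 0.75 (SD, n = 4) to 1.76 ± 1.22 (SD, n = 3; limma adjusted p = 0.0302), with the other groups between, at 1.87 to 4.99. N_FY694ZS02GWEW1 was well above background in all 4 control pools, at -2.46 ± 0.87 (SD, n = 4), and in none of the 3 challenged pools, at -6.74 ± 0.28 (SD, n = 3), so that controls were at least 5.95-fold higher (limma adjusted p = 0.0302); the other groups lay at -4.89 to -1.58.

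Within slides 1, 2 and 3 the challenged minus control difference of P_isotig11699_isogroup01992 was 3.59, 2.98 and 5.16, and that of P_GIDV13C01BU2ZY was 1.90, 1.88 and 0.80. The difference of P_isotig06913_isogroup00450 was -6.51, -4.53 and -2.42, and that of N_FY694ZS02GWEW1 was -3.94, -4.15 and -4.60. A limma fit of the arrays of day 10 alone called 2 probes and kept 0 of the 7. With slide as a block 3 probes were called on day 10, and the adjusted p of P_GIDV13C01BU2ZY and of P_isotig06913_isogroup00450 was 0.067. Leaving out any 1 of 19 of the 24 arrays moved the count by over 1.5 times, from 0 in limma without challenged day 10 replicate 2 (584 at an unadjusted p under 0.05) to 16 without control day 10 replicate 2, and the calls of P_isotig11699_isogroup01992, P_GIDV13C01BU2ZY, P_isotig06913_isogroup00450 and N_FY694ZS02GWEW1 ended in 1, 18, 6 and 5 of the 24 such fits.

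With all arrays in the fit, day 14 held the most calls, with 56 of 9549 probes, 39 higher and 17 lower in challenged clams. In 27 of the 39 that were higher, none of the 3 control pools was well above background, and in 49 of the 56 all pools of the higher group were. N_isotig09852_isogroup01185, with the sequence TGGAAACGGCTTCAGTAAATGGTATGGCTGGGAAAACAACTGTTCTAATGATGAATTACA, was higher in challenged clams by 10.44 ± 2.11 (SE) on the log2 scale, from -3.89 ± 0.35 (SD, n = 3) to 6.55 ± 2.23 (SD, n = 4), and all 7 pools detected it (limma adjusted p = 0.0303). Its signal was 3.21 in challenged day 14 replicate 3 and 7.50 to 7.91 in the other 3. It varied as widely among controls, with -0.41 ± 5.27 (SD, n = 4) on day 10 and 7.35 ± 1.38 (SD, n = 2) on day 31, and its effects on days 10 and 31, which did not pass, were -4.50 and -2.57. N_isotig05662_isogroup00290 was higher in challenged clams by 7.15 ± 1.54 (SE), from -5.19 ± 1.41 (SD, n = 3), with 1 of 3 controls detected, to 1.96 ± 2.12 (SD, n = 4; limma adjusted p = 0.0414). The day 14 controls departed here, since the groups of the other days lay at 0.67 to 3.00. P_isotig25702_isogroup14169, already lower on day 5, fell by 6.81 ± 1.27 (SE), from 2.40 ± 1.29 (SD, n = 3) to -4.41 ± 2.66 (SD, n = 4), with 1 of 4 challenged pools detected (limma adjusted p = 0.019); its controls of the other days lay at -0.49 to 4.74. P_contig00355_isogroup00001 fell by 5.08 ± 0.88 (SE), from -0.79 ± 1.93 (SD, n = 3) to -5.88 ± 0.998 (SD, n = 4), again with 1 of 4 challenged pools detected (limma adjusted p = 0.0138), and the day 14 controls lay above all groups of the other days, at -5.52 to -2.32.

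Within slides 1, 2 and 3 the difference on day 14 was 11.42, 9.61 and 11.45 for N_isotig09852_isogroup01185, and 5.11, 5.47 and 10.96 for N_isotig05662_isogroup00290. It was -6.99, -4.74 and -9.70 for P_isotig25702_isogroup14169, and -3.49, -5.42 and -5.72 for P_contig00355_isogroup00001. With slide as a block 67 probes were called on day 14, and the adjusted p of N_isotig05662_isogroup00290 was 0.0578. Probes well above background on all 24 arrays gave 16 calls, 3 higher and 13 lower, and normexp background correction, which compresses dim signals, gave 7, 2 higher and 5 lower. Without control day 14 replicates 1, 2 or 3 the count was 27, 35 or 21, and without challenged day 14 replicates 2, 3 or 4 it was 33, 34 or 27; without control day 14 replicate 3, day 5 had more calls (24) than day 14 (21). Leaving out 1 array ended the call of N_isotig09852_isogroup01185 in 6 of 24 fits (without control day 14 replicates 1, 2 or 3, adjusted p = 0.0805, 0.0768 or 0.12, and without challenged day 14 replicates 1, 2 or 4, adjusted p = 0.0715, 0.0739 or 0.0734), and those of the other 3 probes in 11, 4 and 1.

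**Figure D2:**
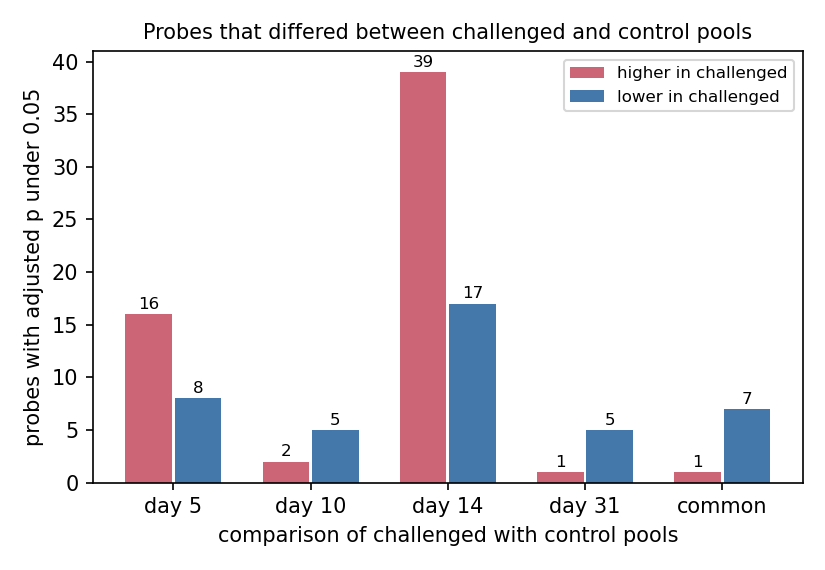
Number of probes with an adjusted p under 0.05 in limma (vertical axis) in each comparison of challenged with control pools (horizontal axis, with common for the effect shared by the 4 days), split into probes higher and probes lower in challenged clams. Day 14 has the most, with 39 higher and 17 lower, and day 31 the fewest, with 1 higher and 5 lower.

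On day 31, 6 of 9549 probes differed, 1 higher and 5 lower in challenged clams. For the 3 probes given, the 2 control pools of day 31 departed, and challenged pools lay at or near the level of the other days. S_isotig15842_isogroup04309 was at -1.02 ± 2.04 (SD, n = 2) in controls and 3.31 ± 0.36 (SD, n = 4) in challenged pools, a difference of 4.33 ± 0.63 (SE) in log2 (limma adjusted p = 0.00774), and the groups of the other days lay at 3.12 to 3.88. N_GIDV13C01DY4BA was at 1.48 ± 2.23 (SD, n = 2) in controls and -5.87 ± 1.59 (SD, n = 4) in challenged pools, with 1 of 4 detected, a difference of -7.35 ± 1.23 (SE) (limma adjusted p = 0.0255), and the other groups lay at -7.18 to -4.86. P_FYX81E202J60LW was well above background in both controls, at -2.91 ± 0.54 (SD, n = 2), and in none of the 4 challenged pools, at -6.94 ± 0.47 (SD, n = 4), so that controls were at least 4.14-fold higher (limma adjusted p = 0.00266). On the other days 1 of 18 arrays detected it.

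Slides 1 and 3 held both groups of day 31, and the differences on them were 6.23 and 2.70 for S_isotig15842_isogroup04309, -6.55 and -6.59 for N_GIDV13C01DY4BA, and -4.16 and -4.02 for P_FYX81E202J60LW. Slide as a block gave 8 calls. With all arrays in the limma fit, 520 of the 9549 probes had an unadjusted p under 0.05 on day 31, where chance gives about 477. Without control day 31 replicate 1 the adjusted p of S_isotig15842_isogroup04309 was 0.111 and that of N_GIDV13C01DY4BA was 0.167, and a limma fit of the 6 arrays of day 31 alone gave 0 calls (477 at an unadjusted p under 0.05). The count was 10 without control day 31 replicate 2 and 3 without challenged day 31 replicate 4.

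An effect shared by the 4 days was tested in a model of day plus challenge. It called 8 probes, 1 higher and 7 lower in challenged clams. P_GIDV13C01DXBQI rose by 2.80 ± 0.53 (SE) on the log2 scale and was well above background in 13 of 14 challenged and 2 of 10 control pools (limma adjusted p = 0.0436). The 2.80 thus rests in part on signals below detection. On days 5 and 31 no control pool detected it, and challenged pools were in the mean at least 6.46-fold and 3.07-fold higher. Its effects on days 10 and 14 were 1.89 and 2.32. None of the 4 days passed by itself (limma adjusted p = 0.284, 0.71, 0.419 and 0.768 on days 5, 10, 14 and 31). P_isotig17799_isogroup06266 fell by 4.97 ± 0.85 (SE) and was detected in 10 of 10 control and 3 of 14 challenged pools (limma adjusted p = 0.0173). No challenged pool of days 5 and 31 detected it. The 1 control array of day 5 was at least 18.3-fold higher, and the controls of day 31 were in the mean at least 11.7-fold higher. The controls of day 31 lay far apart, at -1.41 ± 3.93 (SD, n = 2), so that bound holds for their mean and not for each pool. The effects on days 10 and 14 were -5.22 and -4.51. Again none of the 4 days passed by itself (limma adjusted p = 0.484, 0.343, 0.32 and 0.812 on days 5, 10, 14 and 31). N_FY694ZS02GWEW1 fell by 2.62 ± 0.51 (SE), with 9 of 10 control and 6 of 14 challenged pools detected (limma adjusted p = 0.0436). Its effects of -2.58, -3.06 and 0.07 on days 5, 14 and 31 did not pass, and on day 10 controls were at least 5.95-fold higher. Slide as a block again gave 8 calls and the adjusted p of N_FY694ZS02GWEW1 was 0.0871, and in limma days 10, 14 and 31 without day 5 gave 0 calls (907 at an unadjusted p under 0.05). Leaving out 1 array ended the call of P_GIDV13C01DXBQI in 17 and that of N_FY694ZS02GWEW1 in 18 of 24 fits. The call of P_isotig17799_isogroup06266 ended without control day 5 replicate 1 (adjusted p = 0.0656) or control day 14 replicate 2 (adjusted p = 0.0541). The count was 37 without control day 31 replicate 1, 2 without control day 5 replicate 1 or control day 14 replicate 2, 4 without control day 14 replicate 3, and 5 or 3 without challenged day 10 replicates 2 or 3.

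The challenge effect itself differed between days for 7 of 9546 probes in limma's F test over 3 interaction contrasts. P_isotig17729_isogroup06196 had the smallest p (limma adjusted p = 7.54e-06). It was detected in the 3 challenged pools of day 5 and on none of the other 21 arrays, whose group means lay between -6.82 and -5.58. Its p-values thus rest largely on the spread of signals below detection. S_isotig24587_isogroup13054 was higher in challenged clams on day 14, at -1.99 ± 0.38 (SD, n = 4) against -4.57 ± 0.71 (SD, n = 3), and lower on day 31, at -4.84 ± 0.37 (SD, n = 4) against -1.65 ± 0.98 (SD, n = 2). On day 31 the 2 controls departed, since controls lay at -5.91 on day 5, -4.91 on day 10 and -4.57 on day 14, near the challenged pools of day 31. Control day 31 replicate 2 is 1 of the dim arrays. The effect on day 31 minus that on day 14 was -5.76 ± 0.65 (SE) in log2 (limma adjusted p = 0.000448). On day 14, 4 of 4 challenged and 2 of 3 control pools detected it, and on day 31, 1 of 4 and 2 of 2. The size of the difference thus rests in part on signals below detection. The test includes day 5, whose control is 1 array. A limma fit of days 10, 14 and 31 alone called 6 probes and kept 3 of the 7. A fit with slide as a block called 3 probes, and leaving out any 1 of 12 arrays moved the count by over 1.5 times, from 3 without challenged day 5 replicate 2 to 17 without challenged day 5 replicate 3.

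The time course was tested separately in each arm. Among challenged clams, 43 of 9549 probes changed over the 4 days. P_isotig17729_isogroup06196, detected on day 5 alone, had the smallest p (limma adjusted p = 2.78e-10). S_isotig24587_isogroup13054 followed, with -5.13 ± 0.64 (SD, n = 3) on day 5, -3.72 ± 0.55 (SD, n = 3) on day 10, -1.99 ± 0.38 (SD, n = 4) on day 14 and -4.84 ± 0.37 (SD, n = 4) on day 31 (limma adjusted p = 0.00724). It was detected in 0 of 3, 3 of 3, 4 of 4 and 1 of 4 of these pools. Slide as a block gave 48 calls and array weights gave 301, and leaving out any 1 of 10 arrays moved the count by over 1.5 times, to 9 without challenged day 31 replicate 2.

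Among controls, 34 of 9546 probes changed over the 4 days. N_isotig21703_isogroup10170 was below detection in all 4 control pools of day 10, at -5.47 ± 0.47 (SD, n = 4), and detected in every control pool of day 5, at -2.70, day 14, at -2.36 ± 0.67 (SD, n = 3), and day 31, at -1.96 ± 1.45 (SD, n = 2; limma adjusted p = 0.00832). Challenged pools had the same low point, at -5.34 ± 0.21 (SD, n = 3) on day 10 against -2.62 ± 0.41 (SD, n = 4) on day 14. P_isotig11238_isogroup01754 was lower on the single control array of day 5, at -3.87, than on day 10, at -0.22 ± 0.46 (SD, n = 4), day 14, at 0.61 ± 0.70 (SD, n = 3), or day 31, at 0.22 ± 0.15 (SD, n = 2; limma adjusted p = 0.00832). Without day 5 its adjusted p was 0.527. With slide as a block 38 probes were called, and leaving out any 1 of 8 arrays moved the count by over 1.5 times, to 12 without control day 10 replicate 1.

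**Figure D3:**
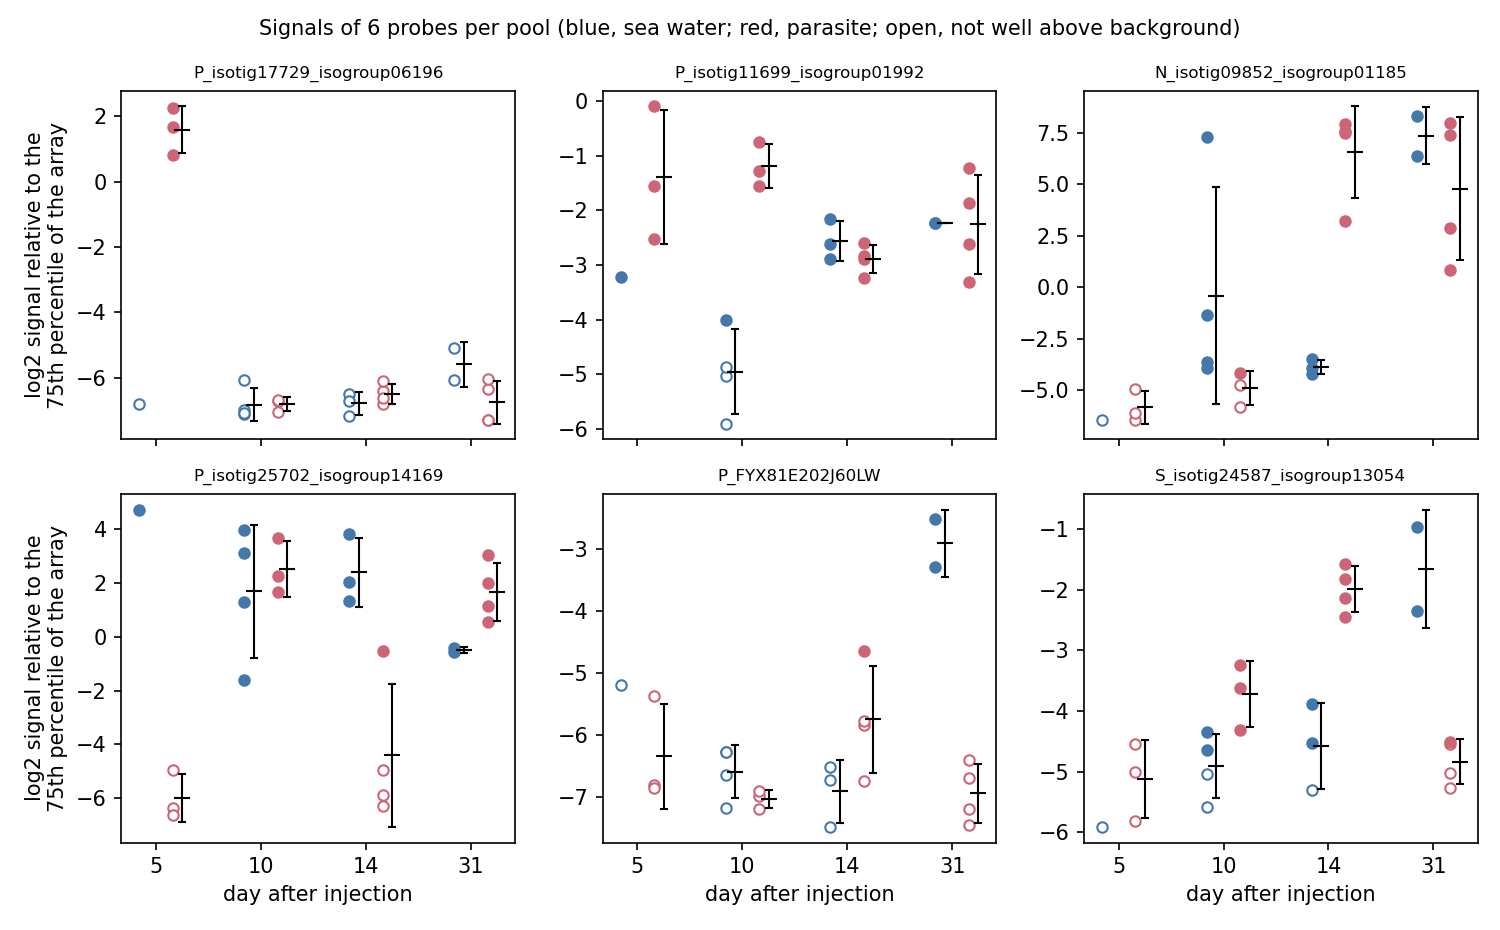
Log2 signal relative to the 75th percentile of the array (vertical axes) by day after injection (horizontal axes) for 6 probes, 1 point per pool, with the group mean and SD in black where a group had over 1 pool. Open points were not well above background. P_isotig17729_isogroup06196 was detected only in the 3 challenged pools of day 5, at 1.58 ± 0.72. S_isotig24587_isogroup13054 was higher in challenged clams on day 14 and lower on day 31, when its control pools departed from controls of the other days.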

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

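The tests of slide for the day 5 and day 14 calls, of noise below detection for the day 14 calls, and the tests of shared sequence and of challenge for the 2 probe sets, were chosen only after the results were seen.

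Among 63 groups of 4 arrays, over the named probes and 2 measures of array signal, 4 held an array far from the other 3, where chance gives about 1 in 20 groups. P_isotig17729_isogroup06196 was at -6.07 in control day 10 replicate 2 and at -7.12 to -6.99 in the other 3, all below detection. N_isotig09852_isogroup01185 was at 3.21 in challenged day 14 replicate 3 and at 7.50 to 7.91 in the other 3. N_GIDV13C01DY4BA was at -3.49 in challenged day 31 replicate 3 and at -6.83 to -6.54 in the other 3. P_isotig17799_isogroup06266 was at -0.40 in challenged day 14 replicate 4 and at -5.34 to -4.65 in the other 3.

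The effect of challenge differed between days for 7 probes in limma's test of the interaction, 4 of which are given here. P_isotig17729_isogroup06196 differed because of its signal in the challenged pools of day 5 (limma adjusted p = 7.54e-06). S_isotig24587_isogroup13054 was higher in challenged clams on day 14 and lower on day 31 (limma adjusted p = 0.00236). On day 31 its 2 controls departed, at -1.65 against -5.91 to -4.57 in controls of the other days. P_FYX81E202J60LW was detected in both control pools of day 31 and in 1 challenged pool of day 14 alone, so most of its signals lay below detection (limma adjusted p = 0.0185 over the 4 days). P_isotig25702_isogroup14169 was at least 512-fold lower in challenged pools on day 5 and had effects of 0.83, -6.81 and 2.18 on days 10, 14 and 31, with 1 of 4 challenged pools detected on day 14 (limma adjusted p = 0.0424 over the 4 days), but none of the 6 differences between pairs of days passed by itself (smallest limma adjusted p = 0.061).

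With all arrays in the fit, the 56 calls of day 14 exceeded those of the other days, but without control day 14 replicate 3 it had 21 and day 5 had 24. Of the 35 splits of its 7 arrays into 4 and 3, only the real one, counted as 1, reached 56. The highest other gave 5. Chance is thus argued against but not excluded, since this share (2.86%) is the smallest that 35 splits allow. The share was not adjusted over the counts tested. Slide is argued against as the whole cause, since 50 of the 56 stayed called with slide as a block. A limma fit of the 7 arrays of day 14 alone called 24 probes and kept 14 of the 56. Effects are the same in that fit, so the other calls depend on the spread estimated from all groups. Noise of spots below detection is argued against as the whole cause, since 16 of the 56 stayed called among probes well above background on all 24 arrays. With a floor at the lowest detectable signal 38 stayed called. However, 1 floor served all arrays and undetected spots can lie above it, so it removes only part of that noise. Normexp correction kept 7, with the median size over the 56 falling from 3.23 (quartiles 2.50 and 4.88) to 1.25 (0.68 and 1.78) in log2. For part of the calls such noise thus stays open. A response to the parasite, or a departure of the day 14 controls as in N_isotig05662_isogroup00290, may underlie the remainder, as a hypothesis found and tested on the same data, and transcripts of the parasite itself stay open because no probe is named.

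The 24 calls of day 5 rest on 1 control array set against 3. When 1 array of a group of 4 was set against the other 3 of its group, 0 of 12 cases gave as many calls. The highest gave 5. A single array against 3 is thus argued against as the whole cause only for arrays like those of these groups. None of them was a dim array, whereas day 5 included challenged day 5 replicate 3, with a 75th percentile of 79.1. The cases therefore cannot decide this for the arrays of day 5 themselves. No slide held both groups of day 5, so a block takes the offset of slide 3, which held the control, from the other days. A slide offset shared by the days is argued against as the whole cause. With slide as a block the effects of the 24 probes kept a median of 0.98 of their size (lowest 0.754), although only 12 stayed called because the other adjusted p rose as far as 0.127. Their median size was 4.35 (quartiles 3.68 and 5.32) before and 4.01 (3.33 and 5.25) after, and standard errors grew by a median factor of 1.06. A slide difference peculiar to the arrays of day 5 cannot be tested here and stays open. A difference peculiar to that control pool could also give such calls and stays open beside the challenge itself.

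A set of 74 probes and a set of 61 probes, found among the 600 most variable probes without use of the arms, varied together in both arms, by -2.67 to 4.83 and -3.12 to 4.67 in mean log2. A shared sequence is argued against for both, since 0% and 0.0546% of their probe pairs shared 15 bases, and slide for the smaller set, with 0.477% of its variance between slides. Array brightness cannot be told apart from other causes, because over 24 arrays Spearman's rho was 0.216 (permutation p = 0.309) and -0.27 (permutation p = 0.2), Pearson's r was 0.029 (permutation p = 0.895) and -0.22 (permutation p = 0.309), and r was 0.23 and -0.119 without the 2 arrays farthest from the median. Slide cannot be excluded for the larger set, with 18.5% of its variance between slides (permutation p = 0.116). Challenge is argued against as the cause, since the probes also varied together among controls. Sets were formed in the 14 challenged arrays alone, and those sharing the most probes with these, 64 and 60, were taken. Their probe pairs had a median correlation of 0.872 and 0.961 among 9 control arrays (at most 0.0755 and 0.0975 in 1000 random sets). The control arrays did not form these sets but had a part in which were taken, which favours a high correlation. The effects of challenge, -0.31 and 0.82, did not pass (exact permutation p = 0.715 and 0.455). A difference between pools of clams may underlie both sets, as a biological explanation that was not tested.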

How the results depend on the processing

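The fit without the 2 dim arrays and that with 1 value per distinct sequence were chosen after seeing the data; the cause of the changes below was not tested, except that fits of 1 day or 1 slide hold fewer arrays. Of the 24 calls of named probes, 18 were challenge effects, of which 0 changed direction under any alternative, and 6 came from F tests, whose largest contrast can be another one under an alternative. That contrast changed sign for S_isotig24587_isogroup13054 in the challenged time course with normexp (3.13 to -1.04) and for P_isotig11238_isogroup01754 in the control time course on days 10, 14 and 31 alone (-3.65 to 0.83), and both calls ended. Of the 24, 9 held in every fit that left out 1 array. Centring on the median, the deposited table, slide as a random block (consensus correlation 0.0559), a minimum log2 change of 1, 1 value per entry of the gene name column (which holds probe identifiers and took the 9549 probes to 9539 values, so this alternative changed little by construction) and 1 value per distinct sequence ended 0 of the 24. Leaving out 1 array ended the call in 2 fits each for P_isotig25702_isogroup14169 and N_isotig15397_isogroup03864 on day 5, and in 6, 11, 4 and 1 for N_isotig09852_isogroup01185, N_isotig05662_isogroup00290, P_isotig25702_isogroup14169 and P_contig00355_isogroup00001 on day 14. It did so in 1 and 4 for S_isotig15842_isogroup04309 and N_GIDV13C01DY4BA on day 31, and in 17, 2 and 18 for P_GIDV13C01DXBQI, P_isotig17799_isogroup06266 and N_FY694ZS02GWEW1 in the shared effect. Quantile normalization and array weights each ended 1, no filter ended 3, the floor 4, slide as a fixed block 5, the fit without the dim arrays 8 and normexp 18. In the order day 5, 10, 14, 31, shared effect, effect differing between days, challenged time course and control time course, the fit of all arrays called 24, 7, 56, 6, 8, 7, 43 and 34. Quantile normalization gave 4 on day 10 (2 higher, 2 lower), and on day 14 it gave 47, with 28 higher and 19 lower against 39 and 17. Normexp background correction gave 5 on day 5 (2 higher), 6 on day 10 (0 higher), 7 on day 14 (2 higher), 2 on day 31 (1 higher), 13 for the control time course, and in limma 0 for the shared effect and 0 for the effect differing between days (447 and 727 at an unadjusted p under 0.05). The floor at the lowest signal well above background gave 13 for the effect differing between days, 59 for the control time course, and on day 5 36 with 14 higher and 22 lower. No filter on dim probes gave 3 on day 10, 10 on day 31, 5 for the shared effect and 54 for the control time course. Probes well above background on all 24 arrays gave 12, 3, 16 and 3 on the 4 days, 15 for the shared effect, 18 for the challenged time course, and 0 in limma for the effect differing between days (494 unadjusted), with fewer probes tested. Array weights gave 2 on day 31, 36, 21, 301 and 17 for the shared effect, the effect differing between days and the challenged and control time courses. Slide as a fixed block gave 14 on day 5, 3 on day 10 and 3 for the effect differing between days. Limma fits within slides 1, 2 and 3, with 1, 2 and 1 residual degrees of freedom, gave 0 for each effect they could hold: day 10 (646, 634 and 660 unadjusted), day 14 (860, 852 and 790), day 31 on slides 1 and 3 (586 and 756), the shared effect (529, 716 and 902), the challenged time course on slides 1 and 2 (682 and 1055) and the control time course on slide 3 (905). The arrays of 1 day alone gave 0, 2, 24 and 0 on days 5, 10, 14 and 31 (670 and 477 unadjusted for the counts of 0). On day 14 the arrays of that day kept 14 of the 56 calls. The replicate number as a block gave 0 in limma on days 10, 14 and 31 and for the shared effect (659, 926, 461 and 869 unadjusted). The 8 same-numbered pairs had r of -0.15 to 0.061, so the numbers do not pair the arrays. An equal-weight mean of the 4 days gave 27 for the shared effect, and days 10, 14 and 31 alone gave 0 (907 unadjusted). Without the 2 dim arrays the counts were 9 on day 5, 1 on day 10, 11 on day 31 and 25 for the effect differing between days. Leaving out 1 array gave 9 to 26 on day 5, 0 to 16 on day 10, 21 to 71 on day 14, 3 to 10 on day 31, 2 to 37 for the shared effect, 3 to 17 for the effect differing between days, 9 to 55 for the challenged and 12 to 51 for the control time course. On day 10, the arrays that left the count within 1.5 times were control day 5 replicate 1, control day 14 replicates 1 and 3, challenged day 14 replicate 4 and challenged day 31 replicate 1. The effect differing between days moved without challenged day 5 replicates 2 (3) and 3 (17), control day 10 replicate 1 (3), challenged day 10 replicates 1 (3), 2 (11) and 3 (3), control day 14 replicate 3 (3), challenged day 14 replicate 4 (4), control day 31 replicates 1 (11) and 2 (12), and challenged day 31 replicates 1 (4) and 2 (4). The challenged time course moved without control day 10 replicate 3 (28), challenged day 10 replicates 1 (23), 2 (18) and 3 (22), challenged day 14 replicates 1 (18), 2 (24), 3 (27) and 4 (15), and challenged day 31 replicates 2 (9) and 3 (16). The control time course moved without control day 10 replicates 1 (12), 3 (20) and 4 (17), challenged day 10 replicates 1 (17) and 3 (17), control day 14 replicates 2 (15) and 3 (22), and control day 31 replicate 2 (18). Without the control array of day 5 the day 5 effect, the effect differing between days and the control time course have no value. The alternatives for the gene lists were not run, since 0 of the 30 lists matched a probe. Signal over background limits the text to the 9549 probes tested, and 28 of the 56 probes called on day 14 were well above background on no array of the lower group.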

Other observations

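The tests of the sets of 7 probes, of the correlation between days 10 and 14 and of slide in another split for the shared effect were chosen only after the results were seen.

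Of the 11 sets of at least 6 probes found among the 600 most variable probes, 2 sets of 7 differed with challenge. The first was higher in challenged clams by 2.27 in mean log2 within days (exact permutation p = 0.00341 over 73500 regroupings within days, 0.0224 adjusted over the 11 sets). Its challenged pools had 1.39 ± 1.28 (SD, n = 3) on day 10 and 3.10 ± 1.45 (SD, n = 4) on day 14, against -1.48 ± 0.59 (SD, n = 4) and -1.78 ± 0.29 (SD, n = 3) in controls. On day 31 they had -1.25 ± 0.28 (SD, n = 4) against -0.43 ± 1.40 (SD, n = 2), and on day 5 0.23 ± 1.39 (SD, n = 3) against -0.16 on the single control array. Controls detected 0, 0, 3 and 1 of the 7 probes on day 10 and 1, 1 and 0 on day 14. The size of the difference thus rests in part on signals below detection. The second was lower in challenged clams, with an effect of -2.02 (exact permutation p = 0.00407, 0.0224 adjusted). Its challenged pools had -1.17 ± 0.29 (SD, n = 3) on day 10 and -1.42 ± 1.65 (SD, n = 4) on day 14, against 2.78 ± 0.92 (SD, n = 4) and 1.37 ± 1.04 (SD, n = 3) in controls. On day 31 they had -1.51 ± 0.33 (SD, n = 4) against -1.95 ± 0.77 (SD, n = 2), and on day 5 0.91 ± 1.45 (SD, n = 3) against 1.13 on the single control array. Members of 1 set may belong to 1 pathway or cell type that responds to challenge, but the 0.0224 tests the mean of each set alone and no member is named.

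A set of 19 probes held 7 of the probes called on day 14, and the first set of 7 held 5 of them. The effect of challenge on the set of 19, 0.67, did not pass (exact permutation p = 0.39). Its mean was 2.70 ± 0.50 (SD, n = 4) in challenged pools of day 14. Controls had 2.88 on day 5, means of -1.27 and -1.64 on days 10 and 14, and -1.30 and 2.61 on day 31. A set of 9 probes, all with the prefix AS and with 15 bases shared by all 36 pairs, was high on challenged day 10 replicate 3, at 6.51, and control day 10 replicate 3, at 5.95, on different slides, and at most 1.87 on the other arrays.

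On day 14, 47 probes were well above background in all challenged pools and no control pool, and 16 the other way round. These numbers were 15 and 8 on day 10, 25 and 18 on day 31, and 117 and 361 on day 5 with its single control. Over all days, 16 probes were well above background on at least 5 challenged arrays and no control array, at most 8 arrays for 1 probe. Regroupings within days gave a median of 11 and at most 114, so it cannot be told whether transcripts present in challenged clams alone, such as those of the parasite, were among them (exact permutation p = 0.319).

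Across probes, which are not independent replicates, the challenge effects of days 10 and 14 correlated at r = 0.132, and the highest of the other regroupings, of 1225 in all, gave 0.202. The exact one-sided permutation p was 0.0498 and 0.299 when adjusted over 6 pairs of days, so a shared response was not shown. Probes called on 2 days numbered 2 for days 5 and 14, 1 for days 10 and 14, and 1, with opposite signs, for days 14 and 31.

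Of the 35 splits of the 7 arrays of day 10, 1, the real one, reached 7 calls and the highest other gave 2. For the shared effect, 2 of 100 splits within days reached 8 calls, the real one included, and the highest other gave 23. That split put 6, 3 and 5 arrays of slides 1, 2 and 3 in its first group, and with slide as a block limma gave it 0 calls (567 at an unadjusted p under 0.05), where the real split gave 8. A structure of the samples along slide is a possible explanation of the 23, which was not tested further. For the challenged time course, 1 of 100 splits, the real one, reached 43 and the highest other gave 4. Chance is argued against for these 3 counts at the 0.05 level, without adjustment over the counts, but is not excluded. For day 10 the share is the smallest that 35 splits allow, and for the shared effect another split gave more calls.

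Probes of prefixes S and AS on 1 contig had a median Pearson correlation of 0.157 over the 24 arrays in 539 pairs, against at most 0.07 in 1000 random pairings, so both may follow 1 transcript in part of the pairs. Of these pairs, 96 exceeded 0.5 and 171 lay below 0.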
